A study of Mus musculus with 14 samples.

How the data were processed

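RNA was measured by bulk, poly-A selected RNA sequencing in the superficial and deep layers of the superior colliculus, a midbrain structure that receives input from the retina, of ICR mice at postnatal day 6. Per the labels' protocols, pups received an injection into the eye between postnatal days 0 and 1 of either saline or carbenoxolone (cbx, a blocker of gap junctions) at 50 mM in 0.3 to 0.5 µL, 3 brains were pooled for each sample, and reads were 150 bases long in pairs.

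The values are whole-number counts of reads per gene, deposited by the authors as 1 table per library with 55359 Ensembl gene IDs each. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.7.9d, SAMtools 1.14, featureCounts and Subread 2.0.1 were used and the genome builds GRCm39 and mm10 are both named, without a role for either. The strand setting and the annotation behind the counts are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and near-identical gene copies may have lost or shared reads. Gene symbols were matched by Ensembl ID for 52083 IDs, which held 98.7% of all counts. Gene types, transcript lengths and GC content came from the GENCODE M21 annotation, used for these properties only and for no coordinates. Total counts ranged from 32004952 to 48776827 per library, and the gene ID with the most counts, which has no symbol, took 0.891% to 1.44% of them.

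Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group, which left 20330 genes. TMM factors scaled the libraries. A quasi-likelihood model with 4 group means was fitted to all 14 libraries (10 residual degrees of freedom, robust dispersion), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values were scaled with TMM factors. Before the data were examined, 37 gene lists, the 5 comparisons, their alternatives and the rule for naming genes were fixed. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 37 lists of a comparison, with an estimated correlation and fry beside it. For each list, members past the threshold were also counted when adjusted over the list alone.

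Genes were named by rule: among protein-coding genes past the threshold, with a mean of at least 1 CPM and no overlap between both groups' libraries, the 10 largest rises and 10 largest falls; for the interaction, where no gene passed, the 5 smallest p-values; and for each list described, up to 4 members with the smallest p-values. Some genes that the rule names are not reported here. Sex-linked, haemoglobin, mitochondrial and ribosomal genes were used only as marks of what the samples held.

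On simulated counts with known changes the test found 96% of 2-fold and 74% of 1.5-fold changes in the superficial cbx comparison, 80% and 58% in the deep one, and 10% and 6% of 1.2-fold changes. At most 0.0646% of unchanged genes were called in any of the 4 group comparisons. Changes below 1.5-fold were therefore found only in part at this depth and number of libraries. The simulated counts were drawn independently for each gene and library, without differences shared between genes or between the layers of a pool. The changed genes all had a mean above 1 CPM. The real libraries may therefore give fewer true and more false calls than these rates.

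Replicate numbers come from the sample titles. Deviations from the group means of same-numbered libraries correlated between the layers of one treatment at 0.264 to 0.645 in all 7 pairs, and 13 of 14 libraries correlated best with the library of their own number. The numbers therefore pair the layers, while the labels do not say that a number marks shared brains. Between treatments the 6 same-numbered pairs correlated at -0.408 to -0.0304, so these share only a number. Counts of the 18 replicate pairs within groups differed by a chi-square of 7.68 to 51.8 per gene, so no pair was a library counted again.

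The alternatives were median-of-ratios size factors, no low-count filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, only the groups compared, each library left out, a test against a fold change of 1.2, and a replicate block. After the data were seen, the following were added: the libraries of the 2 pools of one sex left out, Ddx3y as a covariate, removal of each library's trend with transcript length and GC content (99.6% of tested genes had both), and list tests with libraries left out. The cutoffs on mean CPM for correlations of effects were also chosen afterwards. In the set of pan-neuronal genes written down for a test of dilution, Tubb3 was replaced by Stmn3 before that test was run, because Tubb3 was in a gene list.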

Results

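Gene expression was measured in 14 libraries of the superior colliculus of mouse pups at postnatal day 6, in superficial and deep layers, after eye injection of carbenoxolone (cbx) or saline. The groups held 3 saline and 4 cbx libraries in each layer, each library being a pool of 3 brains, so p-values measure the spread between pooled libraries and not between single pups. The main fit takes the 14 libraries as independent, although same-numbered libraries of both layers deviated together. This limits its p-values. Differences are on the log2 scale unless a CPM is given. Mean total counts were 36807400 (SD 1774880, n = 3) for saline superficial, 35935100 (SD 3580560, n = 4) for cbx superficial, 35078100 (SD 2420560, n = 3) for saline deep and 38360277 (SD 6993470, n = 4) for cbx deep libraries. The first principal component, with 59.3% of the variance of 1000 variable genes, separated the layers.

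**Figure D1:**
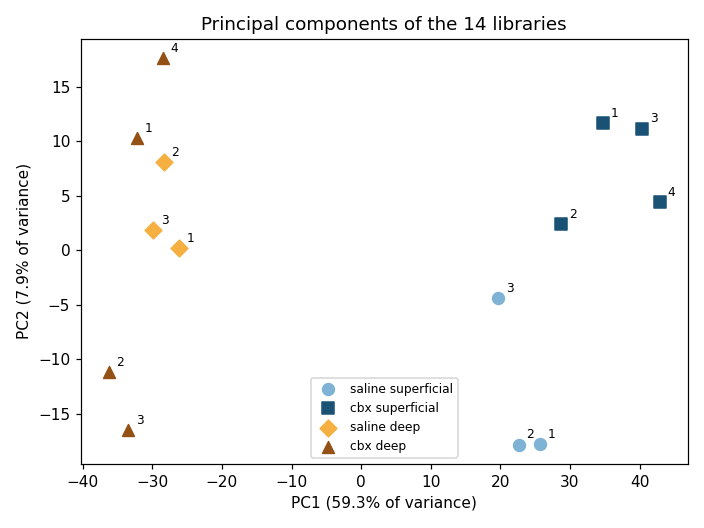
Principal components 1 and 2 of the 14 libraries, from the 1000 most variable genes on the log2 CPM scale; each point is a library, numbers are replicates and colours are groups. All superficial libraries lie to the right of all deep libraries on component 1, which holds 59.3% of the variance.

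The pools differed in sex. Xist, expressed from the inactive X chromosome of females, was at 0.572 and 1.94 CPM in the deep and superficial libraries of saline pool 1 and at 187 to 1127 CPM in the others. Ddx3y, on the Y chromosome, had 0 counts in both libraries of cbx pool 4, which allows up to 0.0875 CPM in the deep and 0.0788 CPM in the superficial one, for counting error only. It ranged from 30.5 to 70.8 CPM in the saline libraries and from 0 to 38.6 CPM in the cbx libraries. The cbx difference of Ddx3y was -1.50 (SE 1.12) in the superficial and -1.31 (SE 1.12) in the deep layer on the log2 scale and did not pass (edgeR adjusted p = 0.504 and 0.657). Saline pool 1 and cbx pool 4 are called the 2 pools of one sex.

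**Figure D2:**
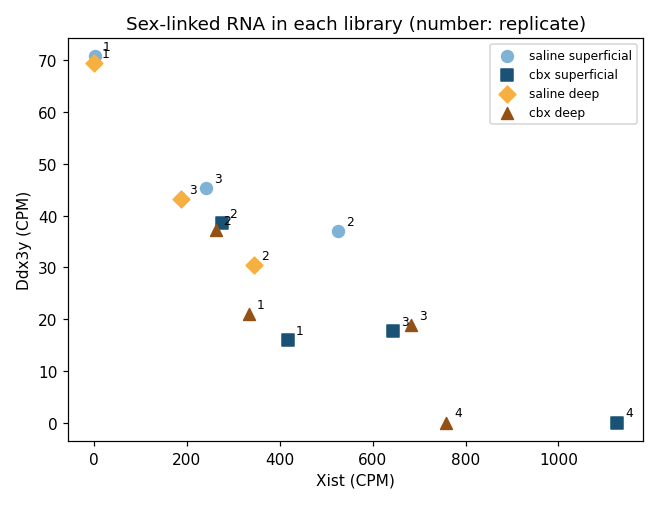
Xist against Ddx3y in CPM, 1 point per library, numbered by replicate. Saline pool 1 has almost no Xist (0.572 and 1.94 CPM) and cbx pool 4 has 0 counts of Ddx3y, in both layers.

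The first comparison asked what cbx, given at the eye to block gap junctions and retinal waves, changed in the superficial layer, which receives the retinal axons. Of 20 genes in the list of microglia and macrophages, called microglial genes below, 9 were higher, and of 21 cholesterol synthesis genes 9 were lower. With an estimated correlation the first list kept its call and the second did not (camera adjusted p = 0.0172 and 0.0509). C1qa (ENSMUSG00000036887), a complement gene of microglia, averaged 40.0 CPM (SD 3.24, n = 4) after cbx and 25.7 CPM (SD 2.17, n = 3) after saline, a log2 difference of 0.64 (SE 0.081, edgeR adjusted p = 0.000686). Insig1 (ENSMUSG00000045294), a regulator of sterol synthesis, averaged 69.2 CPM (SD 8.80, n = 4) and 132 CPM (SD 7.59, n = 3), a log2 difference of -0.93 (SE 0.088, edgeR adjusted p = 3.93e-05). Both kept their direction and their call under the alternatives run for them and with each superficial library left out.

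Of the 20 genes of the microglia and macrophage list, 9 rose and 0 fell, with a median log2 difference of 0.49, and 14 rose when adjusted over the list alone. Besides microglial genes the list holds Pf4, Lyve1 and Mrc1, markers of macrophages at brain borders. P2ry12 rose by 0.37 (SE 0.075), Laptm5 by 0.34 (SE 0.070) and C1qc by 0.49 (SE 0.092). The list passed camera (adjusted p = 4.93e-10) and kept its call with an estimated correlation (adjusted p = 0.0172). Without the 2 pools of one sex its median was 0.48, and with Ddx3y as a covariate 0.41. Of 21 cholesterol synthesis genes, 9 fell and 0 rose, with a median of -0.23, and adjusted over the list alone 15 fell and 2 rose. Besides Insig1, Lss, an enzyme of the pathway, fell by 0.54 (SE 0.087). The list passed camera (adjusted p = 9.18e-10) but not with an estimated correlation (adjusted p = 0.0509). Without the 2 pools of one sex its median was -0.20.

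Of 22 meningeal fibroblast genes, 9 rose and 0 fell, with a median of 0.55, and 13 rose when adjusted over the list alone. Slc22a6 rose by 1.08 (SE 0.23), Pcolce, which aids collagen processing, by 0.89 (SE 0.18), and the transcription factor gene Foxc1 by 0.55 (SE 0.14). The list passed camera (adjusted p = 4.16e-08) and gave an adjusted p = 0.396 with an estimated correlation. Of 9 red blood cell genes 1 rose, Hbb-bt by 0.81 (SE 0.20), and 4 rose when adjusted over the list alone, with a median of 0.73 (camera adjusted p = 0.00433, and adjusted p = 0.396 with an estimated correlation). With Ddx3y as a covariate the red blood cell list did not pass (camera adjusted p = 0.07855). Meningeal, red blood cell and microglial medians were all above 0 in this comparison. Of 13 gap junction and pannexin genes 2 rose, Gjb2 by 1.17 (SE 0.25) and Gjb6 by 1.18 (SE 0.25), and 4 rose when adjusted over the list alone, while the list did not pass (camera adjusted p = 0.0914). Both were also higher in superficial than deep libraries of saline pools, Gjb2 by 2.71 (SE 0.32) and Gjb6 by 1.79 (SE 0.29), as meningeal genes were. Neither passed without saline superficial replicate 2 (adjusted p = 0.112 for Gjb2 and 0.102 for Gjb6) or 3 (0.0940 and 0.0857), with only the superficial libraries in the fit (0.0940 and 0.151), with Ddx3y as a covariate (0.183 and 0.268) or against a fold of 1.2 (0.140 and 0.125). Of 22 myelin genes 3 rose and 1 fell, with Cldn11, also a tight junction gene of the arachnoid, at 1.51 (SE 0.32), and the list had a median of 0.032 (camera adjusted p = 0.681).

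Lists of adhesion, receptor, channel, presynaptic and guidance genes were lower by camera's preset correlation. None of these lists passed with an estimated correlation, and most members of each were not called. Lists of kinds of neurons did not pass camera: immature neurons had a median of 0.105 (adjusted p = 0.136), monoaminergic neurons 0.19 (0.136), thalamic neurons 0.044 (0.583), deep collicular neurons 0.019 (0.650), superficial collicular neurons -0.082 (0.320) and cerebellar neurons -0.086 (0.650). Neuropeptides were at -0.073 (0.583), and cortical and hippocampal neurons at -0.15 (0.986), where camera's direction was up. Of 50 cadherin and synaptic adhesion genes 8 fell and 1 rose, and 16 fell and 2 rose when adjusted over the list alone, with a median of -0.17. Pcdh9 fell by 0.47 (SE 0.088), Cntn3 by 0.47 (SE 0.096) and Cdh6 by 0.42 (SE 0.084). Of 25 glutamate receptor genes 4 fell, and 6 when adjusted over the list alone, with a median of -0.15, Grid1 at -0.31 (SE 0.064) and Grin2a at -0.40 (SE 0.11). Of 29 GABA and glycine genes 4 fell, and 7 when adjusted over the list alone, with a median of -0.072. Gabrg3, a GABA-A receptor subunit, fell by 0.62 (SE 0.14) and Gad2, an enzyme of GABA synthesis, by 0.34 (SE 0.064). Of 41 voltage-gated channel genes 3 fell and 0 rose, and 14 fell and 1 rose when adjusted over the list alone, with a median of -0.20 and the potassium channel gene Kcnq5 at -0.53 (SE 0.10). Of 28 presynaptic genes 1 fell, Vamp1 by 0.28 (SE 0.078), and 4 when adjusted over the list alone, with a median of -0.16. Of 15 acetylcholine genes 1 fell by either adjustment, including that adjusted over the list alone, Ache by 0.22 (SE 0.063), with a median of -0.14. Of 48 semaphorin, slit and netrin genes 4 fell and 1 rose, and 10 fell and 4 rose when adjusted over the list alone, with a median of -0.11 and Sema4d at -0.30 (SE 0.068). These 7 lists passed camera. With an estimated correlation the adjusted p was 0.396 for the adhesion, glutamate, GABA, presynaptic and acetylcholine lists, 0.483 for the channels and 0.736 for the semaphorin list. The semaphorin list did not pass without saline superficial replicate 1 (adjusted p = 0.271), cbx superficial replicate 1 (0.409) or cbx superficial replicate 2 (0.0747), nor without the 2 pools of one sex (0.167), where the GABA list did not pass either (0.0865). With Ddx3y as a covariate the glutamate (0.109), GABA (0.250), acetylcholine (0.160) and semaphorin (0.451) lists did not pass, and after removal of length and GC trends the glutamate (0.130), acetylcholine (0.0602) and semaphorin (0.731) lists did not.

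Of 34 cell cycle genes 1 rose, Ube2c by 0.45 (SE 0.12), the only 1 also when adjusted over the list alone, with a median of 0.15. Of 75 ribosomal protein genes and 21 interferon response genes 0 rose or fell, also when adjusted over the list alone, with medians of 0.16 and 0.37. These lists passed camera (adjusted p = 0.000448, 8.62e-08 and 0.0256), with adjusted p = 0.396, 0.689 and 0.689 with an estimated correlation. The interferon list did not pass without saline superficial replicate 3 (adjusted p = 0.203) or cbx superficial replicate 4 (0.116), nor after removal of length and GC trends (0.0602). With Ddx3y as a covariate the cell cycle list did not pass (camera adjusted p = 0.109). Of 29 activity-regulated genes 1 rose and 2 fell, and 1 rose and 4 fell when adjusted over the list alone, with Btg2 at 0.45 (SE 0.11), Vgf, a neuropeptide precursor, at -0.52 (SE 0.091) and Nptx2 at -0.29 (SE 0.080), and the list did not pass (camera adjusted p = 0.379). Of 22 Eph receptor and ephrin genes 0 were called, also when adjusted over the list alone, and the median was -0.017 (camera adjusted p = 0.453).

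Among the largest rises by the rule were Prdm6, S100a9, Hcar1, Slc47a1, Crabp2, Msr1, C5ar1, Cd209f and Thbd, from 2.75 for Prdm6 (SE 0.62) to 1.70 for Thbd (SE 0.38). S100a9 and C5ar1 are genes of myeloid cells. The largest falls were Alpk3, Gm6356, Cacng1, Lrrc26, Gp1ba, Ciart, Slc22a12, Avil, Xlr3b and Dnah10, with Alpk3 at -1.44 (SE 0.29) and Gm6356 at -1.27 (SE 0.21). Ciart, a repressor in the circadian clock, fell by 1.05 (SE 0.16).

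In all, 880 of 20330 genes passed edgeR's quasi-likelihood test, 545 higher and 335 lower, with a median absolute log2 difference of 0.44 and 112 of them at least 2-fold. Of 82 named genes called here, 15 kept their call with each library left out in turn. The count was 142 with only the superficial libraries in the fit, 379, 140 and 239 without saline superficial replicates 1, 2 and 3, 91 without the 2 pools of one sex and 81 with Ddx3y as a covariate. Removal of length and GC trends gave 598 higher and 593 lower genes, and a filter of 1 CPM in 3 libraries 538 and 551.

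**Figure D3:**
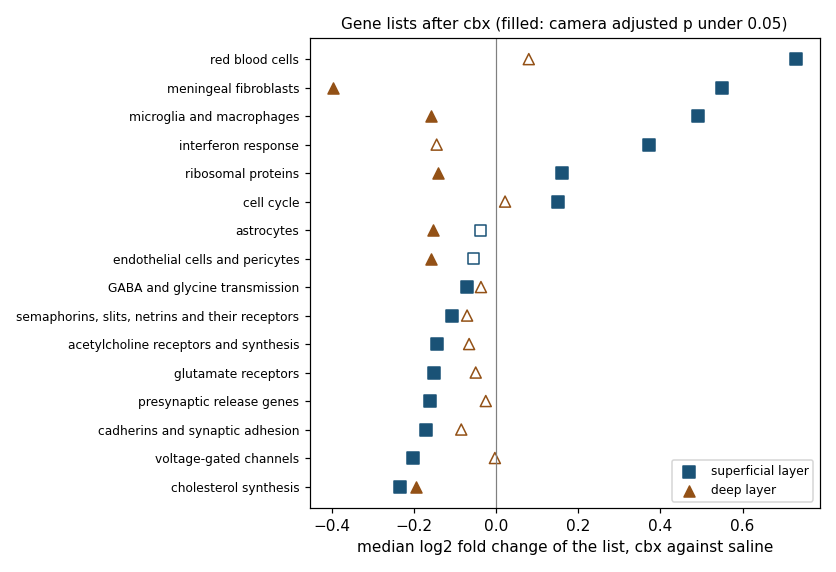
Median log2 fold change, cbx against saline, of the gene lists that passed camera in at least 1 layer; squares are the superficial and triangles the deep layer, and filled symbols passed. Red blood cell, meningeal and microglial lists are at 0.73, 0.55 and 0.49 in the superficial layer, and the cholesterol list is at -0.23 and -0.19 in the superficial and deep layers.

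The same question was asked of the deep layer. Cholesterol synthesis genes were again lower, with 5 of 21 called, in a list that did not pass with an estimated correlation. Insig1 averaged 79.2 CPM (SD 7.07, n = 4) after cbx and 136 CPM (SD 5.08, n = 3) after saline, a log2 difference of -0.78 (SE 0.088, edgeR adjusted p = 0.000514), which kept its call under the alternatives run for it and with each deep library left out. Of 21 cholesterol genes 5 fell and 0 rose, with a median of -0.19, and 9 fell and 1 rose when adjusted over the list alone. Hsd17b7, an enzyme of the pathway, fell by 0.40 (SE 0.074). The list passed camera (adjusted p = 6.98e-08) and gave an adjusted p = 0.199 with an estimated correlation. Without the 2 pools of one sex its median was -0.21.

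Among the largest falls, Pdk4, a kinase that limits glucose oxidation, fell by 1.15 (SE 0.13), and the clock genes Ciart and Per2 fell by 0.93 (SE 0.16) and 0.78 (SE 0.15). The glutamate receptor genes Grid1 and Grik1 fell by 0.31 (SE 0.064) and 0.25 (SE 0.062), and the channel genes Scn2b and Kcna4 rose by 0.50 (SE 0.085) and 0.48 (SE 0.089), in lists that did not pass. Il20rb, Gm6356, Exo1, Pgam2, Cxcr4 and Lars2 were the others of the rule besides Insig1. The largest rises were Fn3k, Kctd21, Gapdhs, Tmem107, AC124108.1, Tmem35b, Tert, Fam161b, Rdm1 and Cdc7, with Kctd21 at 1.29 (SE 0.18) and Cdc7, a kinase of DNA replication, at 0.85 (SE 0.12). The activity-regulated gene Npas4 rose by 0.79 (SE 0.19), the only 1 of 29 in its list, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.129). Npas4 did not pass without saline deep replicate 1 (adjusted p = 0.132), 2 (0.112) or 3 (0.129), nor without cbx deep replicate 2 (0.120), 3 (0.0628) or 4 (0.0838). It also did not pass with limma-voom (0.0793), the replicate block (0.0985), the 2 pools of one sex left out (0.267), Ddx3y as a covariate (0.158) or against a fold of 1.2 (0.428).

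Ribosomal protein, meningeal, microglial, astrocyte and endothelial lists were lower by camera, with medians of -0.14, -0.40, -0.16, -0.15 and -0.16, and none of them passed with an estimated correlation. Of their genes 1 fell, Sox9 of the astrocyte list by 0.42 (SE 0.087). Adjusted over the list alone, 0 ribosomal, 1 meningeal, 3 microglial, 1 astrocyte and 1 endothelial genes fell. With an estimated correlation the adjusted p was 0.688 for the microglial list and 0.898 for the others. Without the 2 pools of one sex the microglial median was -0.089 and the meningeal median -0.46, and with Ddx3y as a covariate they were -0.11 and -0.61. Without saline deep replicate 1 the astrocyte (adjusted p = 0.391), microglial (0.0509) and endothelial (0.0509) lists did not pass. The endothelial list also did not pass without saline deep replicate 2 (0.125) or cbx deep replicates 1 (0.112) and 2 (0.222), nor the astrocyte list without cbx deep replicate 2 (0.0630) or without the 2 pools of one sex (0.464).

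In all, 373 genes passed, 215 higher and 158 lower, 17 of them at least 2-fold. Of 36 named genes called here, 6 kept their call with each library left out in turn. The count was 611 with only the deep libraries, 124, 74 and 42 without saline deep replicates 1, 2 and 3, 114 and 224 without cbx deep replicates 2 and 4, 14 without the 2 pools of one sex, and 122 with Ddx3y as a covariate. Removal of length and GC trends gave 446 higher and 468 lower genes, and the DESeq2 Wald test 448 and 453.

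The cbx calls of both layers shared 99 higher and 64 lower genes and none of opposite direction, where independent lists would share 5.76 and 2.60. Same-numbered libraries of both layers deviated together, so these lists are not independent. The fold changes of both layers correlated across genes at 0.0707 over all 20330 genes, 0.341 over the 15168 with a mean of at least 1 CPM, 0.444 over the 12006 with at least 5 CPM and 0.439 over the 8340 with at least 20 CPM. Regrouped pools gave as high a correlation in 17, 10, 12 and 20 of 35 groupings, the real one included. The covariances were 0.0130, 0.0213, 0.0166 and 0.0115 in the same order, against medians of 0.00670, 0.00735, 0.00565 and 0.00404 in the other groupings, and 11, 2, 2 and 5 of 35 groupings were as large. Genes are not independent replicates.

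**Figure D4:**
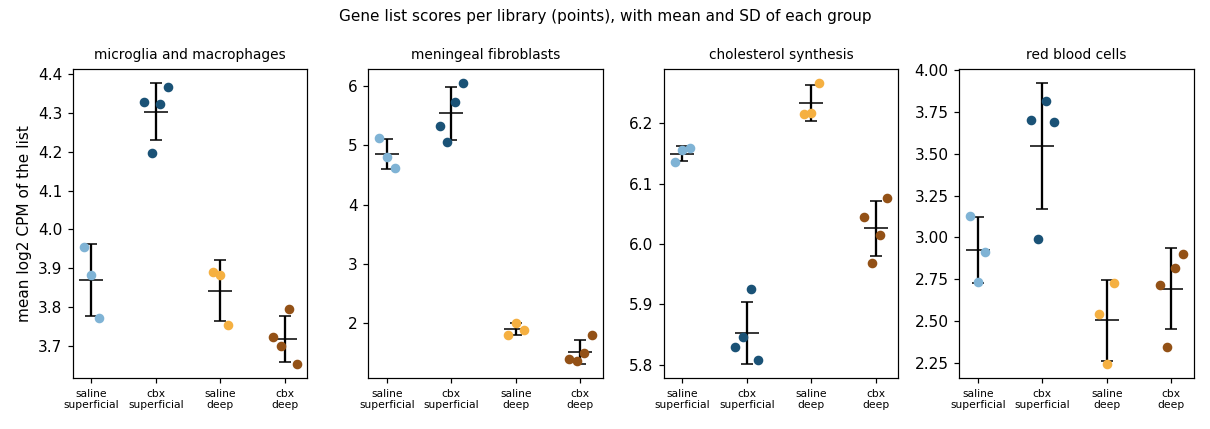
Mean log2 CPM of 4 gene lists in each library (points), with the mean and SD of each group (bars; n = 3 saline and 4 cbx). The 4 cbx superficial libraries (4.20 to 4.37) lie above the 3 saline ones (3.77 to 3.96) for microglial genes, and the cbx libraries lie below the saline ones of their layer for cholesterol genes.

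The third comparison set the superficial against the deep layer after saline. Gfap (ENSMUSG00000020932), a filament protein of astrocytes, was at 455 CPM (SD 86.3, n = 3) in superficial and 6.73 CPM (SD 1.69, n = 3) in deep libraries, a difference of 6.08 (SE 0.46). Of 22 meningeal genes 21 rose, also when adjusted over the list alone, with a median of 2.73, Islr at 2.64 (SE 0.11) and Pcolce at 2.65 (SE 0.22). Of 34 cell cycle genes 29 rose and 0 fell, and 33 rose when adjusted over the list alone, with a median of 0.71 and Top2a, a topoisomerase of dividing cells, at 1.09 (SE 0.12). The cell cycle list kept its call with an estimated correlation (adjusted p = 0.0137), and the meningeal list gave an adjusted p = 0.0650. Ogn, Slc13a4, Fam180a, Ptgds, Fmod, Mrgprf, Mmrn1, Aldh1a2 and Pf4 were the other largest rises, with Ptgds at 301 CPM (SD 103, n = 3) and 8.25 CPM (SD 1.98, n = 3).

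Of 14 neural progenitor genes 7 rose, and 8 when adjusted over the list alone, with Vim at 1.73 (SE 0.078) and Id3 at 1.92 (SE 0.12), and adjusted p = 0.249 with an estimated correlation. Of 23 endothelial and pericyte genes 15 rose and 2 fell, the same numbers as when adjusted over the list alone, with Cldn5 at 1.01 (SE 0.10) and adjusted p = 0.406 with an estimated correlation. Of 20 matrix genes 11 rose and 3 fell, and 11 rose and 5 fell when adjusted over the list alone, with Tnc at 2.10 (SE 0.18) and adjusted p = 0.588 with an estimated correlation. Rorb, a transcription factor of superficial collicular neurons, rose by 1.70 (SE 0.0996).

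Deep libraries had more RNA of the transcription factors Onecut3, Pou4f3, Esrrb and Tfap2d, with Esrrb at -3.31 (SE 0.20). Gm4881, Ppp1r1c, Cdk15, Neu4 and Dgkk were also among the largest falls. Of 12 oligodendrocyte precursor genes 10 fell, and 12 when adjusted over the list alone, with a median of -0.64 and Sox10 at -1.12 (SE 0.074). Of 28 presynaptic genes 16 fell and 1 rose, and 19 fell and 1 rose when adjusted over the list alone, with Syt2 at -1.57 (SE 0.10) and Nefh, a neurofilament gene, at -1.57 (SE 0.12). With an estimated correlation the adjusted p was 0.0650 for both lists. Of 41 channel genes 21 fell and 2 rose, and 24 fell and 2 rose when adjusted over the list alone, with Kcnc4 at -1.42 (SE 0.081) and adjusted p = 0.406 with an estimated correlation. Of 25 glutamate receptor genes 14 fell and 1 rose, the same numbers as when adjusted over the list alone, with Grm2 at -1.09 (SE 0.12) and adjusted p = 0.249 with an estimated correlation. Of 29 GABA and glycine genes 9 fell and 2 rose, and 11 fell and 2 rose when adjusted over the list alone, with Glra3 at -0.97 (SE 0.11), Gad1 at 0.96 (SE 0.072) and adjusted p = 0.377 with an estimated correlation.

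Of 20 microglial genes 14 fell and 3 rose, and 15 fell and 3 rose when adjusted over the list alone, with P2ry12 at -0.99 (SE 0.080) and Cx3cr1 at -0.98 (SE 0.094). The list kept its call with an estimated correlation (adjusted p = 0.0356), with a median of -0.58 and a mean of 0.034. The 3 that rose are markers of macrophages at brain borders: Pf4 was at 5.30 CPM (SD 1.32, n = 3) in superficial and 0.235 CPM (SD 0.198, n = 3) in deep libraries, and Lyve1 and Mrc1, named after their values were seen, rose by 4.29 (SE 0.44) and 2.45 (SE 0.35). Of 22 myelin genes 10 fell and 5 rose, and 10 fell and 6 rose when adjusted over the list alone, with Gpr17 at -1.74 (SE 0.11) and adjusted p = 0.539 with an estimated correlation. Of 13 mitochondrially encoded genes 6 fell, and 7 when adjusted over the list alone, with a median of -0.48 and adjusted p = 0.466 with an estimated correlation. Of 48 semaphorin, slit and netrin genes 19 fell and 8 rose, and 20 fell and 9 rose when adjusted over the list alone, with Nrp2 at 1.66 (SE 0.097) and adjusted p = 0.831 with an estimated correlation. The semaphorin list did not pass without saline deep replicate 1 (adjusted p = 0.193) or saline superficial replicates 2 (0.0722) and 3 (0.0945).

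The lists of superficial and deep collicular neurons did not pass (camera adjusted p = 0.923 and 0.939). Of 14 genes in the first, 7 rose and 6 fell, with Etv1 (-2.20, SE 0.074), Tfap2b (-1.59, SE 0.071) and Cbln2 (-2.04, SE 0.12) higher in deep libraries. Of 14 in the second, 5 rose and 5 fell, with Barhl1 (1.32, SE 0.090) and Sox14 (1.54, SE 0.12) higher in superficial ones. Adjusted over the list alone, 7 rose and 7 fell in the first, and 6 rose and 5 fell in the second. In all 3739 genes passed, 1965 higher in the superficial layer and 1774 lower, and 1780 passed against a fold change of 1.2. The balance turned to 1739 higher and 1994 lower with DESeq2's size factors in edgeR, 1849 and 1990 with a filter of 1 CPM in 3 libraries, 1779 and 1877 without a filter, 1952 and 2230 with the DESeq2 Wald test, and 2170 and 2417 with only the groups compared.

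After cbx the layers differed by many of the same genes. Ptgds, an enzyme of prostaglandin synthesis made in meninges, was at 1230 CPM (SD 677, n = 4) in superficial and 6.76 CPM (SD 3.23, n = 4) in deep libraries, a difference of 7.50 (SE 0.63). Fam180a, Slc13a4, Ogn, Cbr2, Msx2, Mrgprf, Cd209f, Fmod and Wnt6 were the other largest rises, with Fmod at 6.15 (SE 0.42). Pirt, Tfap2d, Onecut3, Esrrb, Gm4881, Pmfbp1, Ppp1r1c, Nts and Pou4f3 were among the largest falls, with Tfap2d at -3.56 (SE 0.23). Of 22 meningeal genes 21 rose, also when adjusted over the list alone, with a median of 4.45 (adjusted p = 0.132 with an estimated correlation). All 34 cell cycle genes rose, also when adjusted over the list alone, with a median of 0.87 and Cdk1 at 1.17 (SE 0.10), and the list kept its call with an estimated correlation (adjusted p = 0.0110).

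Of 41 channel genes 31 fell and 1 rose, the same numbers as when adjusted over the list alone, with Kcnc4 at -1.50 (SE 0.070) and adjusted p = 0.174 with an estimated correlation. Of 25 glutamate receptor genes 20 fell and 1 rose, and 21 fell and 1 rose when adjusted over the list alone, with Grin2d at -0.65 (SE 0.060) and adjusted p = 0.174 with an estimated correlation. Of 75 ribosomal protein genes 51 rose and 0 fell, and 59 rose when adjusted over the list alone, with a median of 0.28, Rpl7 at 0.46 (SE 0.084) and adjusted p = 0.524 with an estimated correlation. Of 21 interferon genes 9 rose, and 10 when adjusted over the list alone, with Ifitm3 at 2.71 (SE 0.15) and adjusted p = 0.524 with an estimated correlation. Of 12 precursor genes 11 fell, and 12 when adjusted over the list alone, with Sox10 at -0.86 (SE 0.064) and adjusted p = 0.152 with an estimated correlation. The lists of presynaptic, endothelial, progenitor, GABA and glycine, cadherin, inflammation, cholesterol, myelin, matrix and semaphorin genes also passed camera, and none of these did with an estimated correlation. The semaphorin list did not pass without cbx superficial replicate 1 (adjusted p = 0.0817). Of 20 microglial genes 7 fell and 4 rose, the same numbers as when adjusted over the list alone, with P2ry12 at -0.55 (SE 0.069), and the list did not pass (median -0.0042, mean 0.60, camera adjusted p = 0.696).

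In all 6544 genes passed, 3671 higher in the superficial layer and 2873 lower, and 3094 passed against a fold change of 1.2. The excess of higher genes was smaller or absent with DESeq2's size factors in edgeR (3258 higher and 3229 lower), a filter of 1 CPM in 3 libraries (3115 and 3185), no filter (3278 and 3119) and the DESeq2 Wald test (3425 and 3495). Of the saline calls, 1688 higher and 1494 lower genes were also called after cbx, against 355 and 251 for independent lists, and 2 genes were called in opposite directions.

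The interaction asked whether the cbx effect differed between layers, as the superficial minus the deep effect. Of 20 microglial genes 0 passed over all genes and 15 were higher when adjusted over the list alone, with a median of 0.50, and the list kept its call with an estimated correlation (adjusted p = 0.00192). Of 22 meningeal genes 14 were higher when adjusted over the list alone, with a median of 1.03, and the adjusted p was 0.267 with an estimated correlation. The smallest p-values belonged to C1qa (0.70, SE 0.11, edgeR adjusted p = 0.105), the meningeal gene Islr (0.85, SE 0.15), the microglial genes Laptm5 (0.55, SE 0.098) and C1qc (0.71, SE 0.13), and Mxi1 (0.49, SE 0.093).

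No gene passed in edgeR, with 1699 of 20330 at an unadjusted p under 0.05, 60 called by the DESeq2 Wald test and 0 by limma-voom. With the replicate block, which pairs the layers, 61 genes passed, 55 higher and 6 lower, among them C1qa (edgeR adjusted p = 0.00364), Islr (0.000873), Laptm5 (0.00944), C1qc (0.00527) and Mxi1 (0.0239). With the block, 1 of the 34 other groupings of the pools gave 1141. Over the alternatives, the adjusted p of C1qa also was 0.131 with limma-voom and 0.000177 with DESeq2. Without cbx superficial replicate 2 the count was 14, and without cbx superficial replicate 4 it was 1. Camera passed 14 lists here, and all but the microglial one had an estimated-correlation adjusted p of at least 0.267.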

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

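All tests here but those of regrouped libraries without the block were chosen after the patterns were seen, and for time of day, sex as a cause of the cholesterol pattern, length and GC, and dilution the bounds were written before the test's own result. In 161 sets of 4 libraries, 13 held a library whose gap to the nearest other was a large part of the range; chance gives about 1 in 20. Among the 4 cbx deep libraries, replicate 1 had the highest total (0.878 of the range, 48776827 counts), the highest hypoxia and heat shock score (0.914), the lowest Ciart (0.911, 2.93 CPM) and the highest Wnt6 (0.912, 0.335 CPM). Cbx pool 4 stood apart in the sex-linked list in the superficial (0.849) and deep (0.851) layer. Among the 4 cbx superficial libraries, replicate 2 had the lowest red blood cell score (0.852). Within the cbx deep group, replicate 2 had the lowest cerebellar score (0.855) and Rdm1 (0.900) and the highest Pmfbp1 (0.911). In that group Msx2 (1 of the range, 0.117 CPM) and Cd209f (0.856, 0.204 CPM) were highest in cbx deep replicate 3 and Mrgprf (0.854, 0.206 CPM) in cbx deep replicate 4.

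The cbx effect differed between layers by camera for 14 lists, as superficial minus deep median: microglia 0.50, meningeal fibroblasts 1.03, interferon response 0.61, ribosomal proteins 0.30, inflammation and reactive glia 0.26, neural progenitors 0.23, mitochondrially encoded genes 0.23, oligodendrocyte precursors 0.19, red blood cells 0.18, cell cycle 0.14, glucocorticoid response 0.14, cadherins and synaptic adhesion -0.12, voltage-gated channels -0.19 and presynaptic genes -0.096. Of these only the microglial list passed with an estimated correlation (adjusted p = 0.00192). Without saline deep replicate 1 the interferon median was 0.27 and the interferon (camera adjusted p = 0.176), presynaptic (0.0536) and precursor (0.0690) lists did not pass. The adhesion list did not pass without saline deep replicate 3 (0.112), cbx deep replicate 1 (0.0586) or cbx superficial replicate 1 (0.0805). The presynaptic list also did not pass without saline deep replicates 2 (0.0612) and 3 (0.0785), saline superficial replicate 3 (0.468), cbx deep replicate 1 (0.278) or cbx superficial replicate 4 (0.0856). Without cbx superficial replicate 3 the red blood cell, precursor and glucocorticoid lists did not pass (0.0553 each), nor did the red blood cell list without saline deep replicate 3 (0.0785) and the glucocorticoid list without cbx deep replicate 4 (0.0686) or cbx superficial replicate 4 (0.0508). The red blood cell median ranged from 0.081 without cbx deep replicate 2 to 0.44 without cbx superficial replicate 2.

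In the superficial cbx comparison the real split was the only 1 of 35 with as many genes called (880, highest other split 119). The same held in the deep one (373, highest other 3). This argues against chance but does not exclude it. A share of 1 in 35 is the smallest these splits can give, and the layers are paired, so both results are not independent. Between layers after cbx (6544, highest other 1) the real split also was the only 1 of 35 as large. But the numbers pair the layers, and the 8 splits that part every pair (highest other 0) are too few for a share under 0.05. The 10 splits of the saline libraries are too few for a share under 0.05, for genes (3739, highest other 0) and for lists (14, highest other 16). For the interaction 0 genes were called (highest other 1), so all 35 splits count as large and the test says nothing. With the replicate block chance cannot be excluded for its 61 genes, as 2 of 35 splits gave as many. The other, with cbx pools 1 to 3 against the rest, moves only cbx pool 4 and gave 1141, which points to a structure of the samples that was not tested. Without the block the same split gave 0. For the 18 lists of the interaction with the block the real split was the only 1 of 35 as large (highest other 16). That test was added after the data were seen, and the split with 16 lists is the one that gave 1141 genes, so it does not exclude chance. Nor can chance be excluded for the numbers of lists by camera's preset correlation without the block: 5 of 35 splits gave at least the 14 of the superficial cbx comparison (highest other 15), 22 the 6 of the deep one (16), 2 the 17 between layers after cbx (17) and 3 the 14 of the interaction (15).

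Microglial and meningeal lists were higher in the cbx superficial libraries by camera, with adjusted p = 0.0172 for the first and 0.396 for the second with an estimated correlation. More meninges in these dissections may account for the meningeal part. The 17 meningeal genes at least 4-fold higher in the superficial layer of saline pools had a median of 0.57 (SE 0.28 over libraries). These genes belong to the list that raised the question (median 0.55, all 22 genes above 0), so their rise restates the pattern and cannot test this. More meninges is argued against for the microglial part, since 10 genes of microglia inside the tissue, lower in the superficial layer of saline pools (median -0.72), had a median of 0.44 (SE 0.022), 9 of 10 above 0. A lower share of neurons that raises all other cell types alike is argued against as the whole cause, since astrocyte, precursor and endothelial genes lay below microglial genes (-0.54, SE 0.058). The medians of these lists had been seen before that comparison was set. A change in microglia after cbx remains open as a hypothesis. Without the 2 pools of one sex the microglial list had a median of 0.48.

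The cholesterol synthesis list was lower in both layers by camera, with 9 superficial and 5 deep calls among 21 genes, and adjusted p = 0.0509 and 0.199 with an estimated correlation. Unequal sex of the pools is argued against as the whole cause: without the pools of one sex the median was -0.198 (SE 0.029) in the superficial and -0.206 (SE 0.034) in the deep layer. Leaving them out did not balance sex: Ddx3y was at 30.5 and 43.3 CPM in the remaining saline deep libraries and at 20.9, 37.2 and 18.9 CPM in the remaining cbx deep ones. With Ddx3y as a covariate the medians were -0.26 in the superficial and -0.24 in the deep layer. Fewer oligodendrocytes cannot be told apart, as their genes had a median of 0.0092 in the superficial layer, with an SE of 0.22. In the deep layer their median was -0.035, beside -0.19 for the cholesterol list. An effect of cbx on sterol synthesis remains open as a hypothesis. A different time of day at dissection cannot be told apart, as clock genes of both phases were lower: their difference was 0.075 (SE 0.058) in the superficial and -0.11 (SE 0.039) in the deep layer.

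Neuronal channel, receptor and adhesion lists were lower by camera in the cbx superficial libraries, with a median of -0.15 (SE 0.064) over 160 genes. Of these 8 adhesion, 4 glutamate, 4 GABA and glycine, 1 acetylcholine and 3 channel genes were called lower, and the 5 lists had an adjusted p of 0.396 to 0.483 with an estimated correlation. After removal of length and GC trends the median was -0.10, so a trend may account for part. The median kept 67.6% of its size, which by a small margin met the bound written beforehand for arguing against a trend. The spread of the difference between both medians was not measured, so a trend cannot be told apart. Dilution by other RNA cannot be told apart either: 10 pan-neuronal genes had a median of -0.10 (SE 0.069), 8 of them below 0 and 0 past the threshold. An effect of cbx itself remains open as a hypothesis.

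Fewer genes were called without the 2 pools of one sex (91 superficial). Their sex is argued against as the whole cause, since 6 of the 11 other choices of 1 saline and 1 cbx pool gave as few.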

How the results depend on the processing

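The added alternatives (2 pools of one sex left out, the Ddx3y covariate, and removal of length and GC trends) were chosen after seeing the data. No call of a named gene or list changed sign in any alternative, and 292 of 493 named gene and list results stayed on their side of the threshold in all. For most changed counts the cause was not tested. Superficial cbx calls (880) became 1459 without a filter, 1585 with DESeq2, 35 against a fold of 1.2, 142 with only the groups compared, 91 without the 2 pools of one sex and 81 with Ddx3y, and ranged from 140 to 907 with a library left out. Deep cbx calls (373) became 566, 901, 4, 611, 14 and 122 under the same settings, and 914 after removal of length and GC trends, and ranged from 42 to 272. Leaving out 2 pools removes libraries as well as part of an imbalance of sex. Of the 11 other choices of 1 saline and 1 cbx pool, 6 gave as few superficial calls (median 78) and 7 as few deep calls (median 3), so the fall is no larger than the loss of libraries gave, while the Ddx3y covariate shares the treatment's direction. Layer calls after saline (3739) ranged from 2685 to 3406 and after cbx (6544) from 5391 to 6276 with a library left out, and were 1780 and 3094 against a fold of 1.2. The interaction (0) gave 256 without a filter, 60 with DESeq2 and 61 with the replicate block, and 0 to 14 with a library left out. Across treatments, where numbers do not pair the samples, the replicate block gave 480 superficial and 191 deep calls. Between layers, where the numbers pair the samples, the block gave 4662 calls after saline and 7602 after cbx, and 18 lists for the interaction, and besides the 5 interaction genes named it ended or made no call of a named gene. With an estimated correlation the lists past the threshold were 1, 0, 2, 1 and 1 for the superficial cbx, deep cbx, saline layer, cbx layer and interaction comparisons, against 14, 6, 14, 17 and 14. In the same order fry gave 4, 1, 18, 24 and 1, so it passed more lists than camera between layers and fewer elsewhere. With a library left out the lists ranged from 13 to 17, 3 to 12, 13 to 16, 17 to 18 and 13 to 19. Of deep lists, 3 passed without saline deep replicate 1, 11 without saline deep replicate 3 and 12 without cbx deep replicate 3. At this depth and number of libraries, 10% of simulated 1.2-fold superficial changes were called.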

Other observations

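The interferon list averaged 1.38 log2 CPM in saline deep replicate 1, against 0.272 and -0.0574 in saline deep replicates 2 and 3 and 0.181 to 0.283 in the cbx deep libraries. It averaged 1.24 in saline superficial replicate 1, against 0.797 and 0.540 in saline superficial replicates 2 and 3 and 0.994 to 1.37 in the cbx superficial libraries. The list of cortical and hippocampal neurons averaged 3.24 log2 CPM in saline superficial replicate 3, against 2.14 and 2.28 in saline superficial replicates 1 and 2.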
